A study of Mus musculus with 12 samples.

How the data were processed

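RNA from a section of the left ventricle of C57/Bl6 mice was hybridised to 12 Agilent whole-genome mouse arrays in a single colour (Cy3), per the labels, with 3 arrays in each of 4 groups: wild-type and CnAb1 transgenic hearts, each after sham surgery or TAC. All groups were taken 21 days after surgery by the protocol and the source names; a separate time label gives 0 for the sham groups, and day 21 was used for all. The array files hold spot signals in units of intensity, per the file headers, from Feature Extraction 10.7.3.1: a processed signal with background subtracted and spatial trends removed, not scaled between arrays, and the median brightness of each spot and of its surroundings. The deposited table of values is in log2 units; its values match log2 processed signals scaled by a percentile of each array and centred on each probe's median over the 12 arrays. The submitters' processing notes name RMA; what it was used for is not given in the sources used here.

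The processed signal was read for 43020 non-control spots. Spots marked as outliers in the files were left out, replicate spots of a probe were averaged, and each array's 75th percentile was subtracted on the log2 scale. Probes were named through their transcript accessions with a gene table of the mouse assembly GRCm38.p6; the array annotation names the older build mm9, so no positions are given, and the assembly served only for names and gene order. Of 39429 probes, 26424 received a symbol, 20021 symbols in all, and 13005 kept their probe name. Probes well above background on at least 3 of the 12 arrays were kept, with the brightest probe taken for each gene, which left 25321 genes, 16653 of them named. A group in which a gene was well above background on 0 arrays counts as at background, and a change against it is given as a lower bound, against each array's lowest signal well above background or the gene's own signal where that is higher. No pair of arrays held identical values.

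The groups were compared with limma 3.58.1 in R 4.3.3: a mean per group over all 12 arrays, the contrasts TAC against sham in each genotype, transgenic against wild type in each surgery, the interaction, which is the transgenic TAC response minus the wild-type one, and the averages over genotypes and over surgeries. The moderated tests were two-sided and had 8 residual degrees of freedom and 1.79 prior ones; the median residual standard deviation was 0.27 on the log2 scale. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the adjustment was also made over each list alone. Of 36 gene lists covering cardiac, matrix, signalling, metabolic and stress genes and markers of other cell types, 35 had at least 3 measured members; the list of mitochondrially encoded genes had none and was not tested. The lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move, on balance, one way. Past the threshold under the preset value were 18 lists for TAC in wild-type hearts, 8 for TAC in transgenic hearts, 17 and 16 for genotype in sham and in TAC, and 18 for the interaction; with an estimated correlation 1, 0, 0, 0 and 0 remained, and fry passed 17, 0, 8, 9 and 14 of them.

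The groups, tests, gene lists, the other settings to try and the rule for named genes were set before the data were examined. By that rule the text names up to 10 genes in each direction by size of change among those that passed and, in comparisons of 3 arrays with 3, did not overlap, leaving out clone and predicted names. It also names 15 core genes whatever their test, up to 4 members of each described list with the smallest p, and, where no gene passed, the 5 with the smallest p in each direction. Only genes in that rule, other probes of the same gene, and the genes with a constant genotype difference, which were chosen after their values were seen, are named. Some genes in that rule are not reported here.

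Most alternatives changed a choice at a time: quantile normalization, median scaling, normexp background correction with an offset of 50, both together, the deposited table, no filter, a filter on all 12 arrays, outlier spots kept, the mean over a gene's probes, a trended robust variance, array weights, the compared groups alone, an unmoderated test, a block on replicate number, slide as a fixed block, and each array left out. The files hold median but no mean spot brightness, so normexp used the medians. It therefore replaced the processed signal, with its background subtraction and spatial detrending, as well as the correction, and a move under it cannot be put down to the correction alone. Normexp with quantile normalization changed the scaling as well. A common floor and slide as a random block were added later. The barcoded slides, 5 in all, served as the batch. The steps were tested on simulated data: of 100 genes moved by 2 on the log2 scale between wild-type groups 79% were recovered, and of 100 moved by 1, 42%, with 7 calls among genes that were not moved. There 4 of 200 random lists had p under 0.05 by camera. The simulated genes were drawn independently, so this does not check the preset correlation on real genes, which move together.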

Results

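Left ventricular RNA was measured on 12 single-colour arrays from mice that overexpressed CnAb1, a splicing variant of the calcineurin A beta catalytic subunit, and from wild-type mice. Hearts were taken 21 days after transverse aortic constriction (TAC) or a sham operation. TAC places a band around the aorta that raises the pressure load on the left ventricle. The 4 groups, wild-type sham, wild-type TAC, transgenic sham and transgenic TAC, held 3 arrays each. The labels do not say whether each array came from a separate animal, so the p-values measure the spread between arrays. Transgenic sham array 2 had a raised background: its negative controls gave a net signal of 48.6, against 15.4 to 21.0 on the other arrays. On that array 14672 of 39429 probes (37.2%) stood well above background, against 23760 to 30830 (60.3% to 78.2%) on the others. The median standard deviation of a gene's log2 signal within a group was 0.10 in wild-type sham, 0.13 in wild-type TAC, 0.18 in transgenic sham and 0.14 in transgenic TAC, over the 12316 genes well above background on all 12 arrays. The number of arrays limits the precision of every value. Changes below are log2 differences ± standard error between groups of 3 arrays, with limma p-values adjusted over all 25321 genes tested unless stated.

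The comparison of TAC with sham in wild-type hearts asks what pressure overload does to the left ventricle without the transgene. Genes of the extracellular matrix rose by large amounts: Comp by 6.59 ± 0.78, Cilp by 6.28 ± 0.47, Ltbp2 by 6.17 ± 0.50, Postn (periostin, secreted by activated fibroblasts) by 5.41 ± 0.40 and Col5a2 by 4.93 ± 0.32 (adjusted p from 0.000362 to 0.00131). The fetal cardiac genes Myh7, the slow myosin heavy chain, Nppa and Nppb, the natriuretic peptides, rose by 3.40 ± 0.36, 2.97 ± 0.35 and 2.07 ± 0.40 (adjusted p from 0.000809 to 0.00692). Rcan1, a calcineurin inhibitor whose transcription responds to calcineurin itself, rose by 1.49 ± 0.19 (adjusted p = 0.00175). Atp2a2, the calcium pump of the sarcoplasmic reticulum, changed by -0.95 ± 0.13 (adjusted p = 0.00198), and Ppargc1a, a coactivator of mitochondrial biogenesis, by -1.80 ± 0.37 (adjusted p = 0.0084). Acta1, skeletal alpha-actin, measured 1.74 ± 0.72 and did not pass (adjusted p = 0.122).

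Other genes with large increases after TAC in wild-type hearts were Ecrg4 (5.73 ± 1.25), Dkk3 (4.80 ± 0.60), Frem1 and Atp6v0a4. Frem1 and Atp6v0a4 were at background on sham arrays, so their increases were at least 7.29-fold and at least 12.7-fold. Large falls among genes named by the fixed rule included Pde5a, a phosphodiesterase of cyclic GMP (-4.78 ± 1.11), Slc49a4 (-3.88 ± 1.06), Retnla (-3.79 ± 0.79), Olfr441 (-3.59 ± 0.87), Emilin3 (-3.35 ± 0.96), Acsm5 (-3.27 ± 0.63), Ces1d (-3.16 ± 0.61) and Olfr362 (-3.16 ± 0.92). Lcn6 measured -3.17 ± 0.67 on its tested probe and -0.41 on its other probe, which did not pass (adjusted p = 0.418). For each of these top genes the 3 TAC arrays did not overlap the 3 sham arrays, as the rule for naming them required. Of the other core genes, Col1a1 rose by 3.63 ± 0.35 and Mthfd2, an enzyme of mitochondrial folate metabolism, by 2.79 ± 0.72, and Ppp3cb changed by -0.31 ± 0.10 (adjusted p = 0.0471). Phgdh (0.73 ± 0.60), Psat1 (1.14 ± 0.64), Shmt2 (-0.23 ± 0.17) and Atf4 (0.20 ± 0.47) did not pass.

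By gene group, 45 of 47 measured extracellular matrix genes rose after TAC in wild-type hearts, 0 fell and 2 did not pass, with 45 rising adjusted over the list alone. Their median was 2.78 (adjusted p = 2.51e-43 by camera, and adjusted p = 0.112 with an estimated correlation). Of 10 fetal and hypertrophy genes 6 rose, 0 fell and 4 did not pass, with 6 adjusted over the list alone. Their median was 1.67, with Ankrd1 at 1.60 ± 0.21 and Xirp2 at 1.73 ± 0.26 (camera adjusted p = 2.34e-06; adjusted p = 0.0413 with an estimated correlation). Marker lists of some other cell types had medians above 0 as well, while others, such as T and NK cell and Schwann and nerve markers, had medians below 0. Fibroblast markers had a median of 0.65, with 6 of 11 higher and 6 adjusted over the list alone, Pi16 at 2.08 ± 0.19 and Meox1 at 2.47 ± 0.29 (adjusted p = 0.112 with an estimated correlation). Macrophage and monocyte markers had a median of 0.36, with 4 of 15 higher and 4 adjusted over the list alone (adjusted p = 0.287 with an estimated correlation), among them Fcgr1 at 1.33 ± 0.26 and Lgals3 at 2.60 ± 0.69. Endothelial markers had a median of 0.64, with 6 of 12 higher and 1 lower, and 8 and 1 adjusted over the list alone (adjusted p = 0.184 with an estimated correlation). Smooth muscle and pericyte markers had a median of 0.60, with 5 of 10 higher and 1 lower, and 5 and 1 adjusted over the list alone (adjusted p = 0.216 with an estimated correlation). Proliferation genes had a median of 1.62, with 5 of 9 higher and 1 lower, and 5 and 1 adjusted over the list alone (adjusted p = 0.353 with an estimated correlation). With slide as a block that median was 1.04. Mki67 measured 2.35 ± 0.49. Inflammatory cytokine genes had a median of 0.35, with 6 of 23 higher, 0 lower and 6 adjusted over the list alone, including Cxcl10 at 2.59 ± 0.49 and Il33 at 2.09 ± 0.41 (adjusted p = 0.244 with an estimated correlation). With probes well above background on all 12 arrays that median was 0.13 and past no threshold. Of 13 immediate early genes 2 rose, Myc (1.91 ± 0.36) and Egr2 (4.09 ± 1.00), and 2 adjusted over the list alone. The list's median was 0.56 (adjusted p = 0.491 with an estimated correlation), and it was -0.07 with slide as a block and 0.30 with probes well above background on all 12 arrays, past no threshold in either.

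Genes of mitochondrial energy metabolism fell together in wild-type hearts after TAC, relative to each array's 75th percentile. Before scaling, that percentile was 8.97 to 9.24 (log2) on wild-type sham and 9.88 to 9.95 on wild-type TAC arrays. On transgenic arrays it was 9.50 to 9.51 after sham and 9.48 to 9.86 after TAC. The scaling subtracts this shift, which is about as large as the list medians below. Of 78 measured oxidative phosphorylation genes 75 fell, 0 rose and 3 did not pass, with 76 falling adjusted over the list alone. Sdhc measured -0.92 ± 0.10 and Atp5a1 -0.77 ± 0.09. The list's median was -0.73 (camera adjusted p = 4.54e-31; adjusted p = 0.184 with an estimated correlation), and -0.29 under quantile normalization. Of 28 fatty acid oxidation genes 27 fell, and 27 adjusted over the list alone, with a median of -0.92. Eci1 measured -1.36 ± 0.14 and Hadha -1.32 ± 0.14 (camera adjusted p = 3.06e-17; adjusted p = 0.112 with an estimated correlation). All 18 tricarboxylic acid cycle genes fell, by both adjustments, with a list median of -0.68 (adjusted p = 0.112 with an estimated correlation). Of 76 mitochondrial ribosome genes 44 fell and 0 rose, with 57 falling adjusted over the list alone and a median of -0.48 (adjusted p = 0.334 with an estimated correlation). Of 20 mitochondrial biogenesis and dynamics genes 10 fell, Mfn2 and Esrra among them at -0.57 ± 0.11 and -0.71 ± 0.14, with 13 falling adjusted over the list alone and a median of -0.42 (adjusted p = 0.112 with an estimated correlation). Of 13 mitochondrial chaperone and protease genes 6 fell, with 9 falling adjusted over the list alone and a median of -0.50 (adjusted p = 0.287 with an estimated correlation).

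The medians of ion-handling and of sarcomere genes of the adult cardiomyocyte were also below 0 after TAC in wild-type hearts. The sarcomere median was not below 0 under quantile normalization. Of 21 ion channel and calcium handling genes 13 fell and 0 rose, with 15 and 1 adjusted over the list alone. The potassium channel gene Kcnj2 measured -1.22 ± 0.12 and Hrc -1.23 ± 0.17. The median was -0.58 (camera adjusted p = 2.18e-05; adjusted p = 0.112 with an estimated correlation). Of 21 sarcomere genes 10 fell and 1 rose, with 11 and 1 adjusted over the list alone. Tnni3 measured -0.93 ± 0.12 and Myh6, the fast myosin heavy chain, -0.76 ± 0.11. The sarcomere median was -0.43 (adjusted p = 0.287 with an estimated correlation), but it turned to 0.05 under quantile normalization. Of 19 glycolysis genes 8 fell and 1 rose, with 10 and 1 adjusted over the list alone. Slc2a4 measured -1.02 ± 0.14. The glycolysis median was -0.35 (adjusted p = 0.334 with an estimated correlation), and it turned to 0.03 under quantile normalization.

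Over all genes, 5377 of 25321 passed for TAC against sham in wild-type hearts, 2204 higher and 3173 lower. Of these, 1638 changed by more than 2-fold, 980 higher and 658 lower. The 3 and 3 arrays did not overlap for 46.8% of genes, where chance gives 10%. The median of all genes was -0.13, and normexp background correction moved it to 0.25 and gave 1497 genes, 1488 of them among the 5377. With slide as a block 524 genes passed, and 351 of these were among the 5377. Between the wild-type arrays that shared slide 2 the matrix, oxidative phosphorylation and fatty acid oxidation medians were 2.02, -0.63 and -0.81, from 1 TAC array against 2 sham arrays. With slide as a block they were 2.23, -0.69 and -0.82. Without wild-type TAC array 3, wild-type sham array 1 or wild-type sham array 3 the count was 2813, 2884 or 3219.

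The same comparison in transgenic hearts asks whether overexpression of CnAb1 leaves that response in place. No gene passed: limma called 0 of 25321 genes, with 1575 at an unadjusted p under 0.05. A fit to these groups alone and an unmoderated test of each gene also called 0, with 781 and 924 genes at an unadjusted p under 0.05. The 3 and 3 arrays did not overlap for 8.44% of genes, where chance gives 10%. Postn measured 1.03 ± 0.40, Cilp 1.21 ± 0.47, Rcan1 0.65 ± 0.19, Nppa 0.39 ± 0.35, Nppb 0.10 ± 0.40, Col1a1 0.16 ± 0.35 and Myh7 -0.24 ± 0.36. Acta1 measured 2.33 ± 0.72 and Phgdh -1.81 ± 0.60 (adjusted p = 0.797 for both). Psat1 measured -1.30 ± 0.64, Shmt2 -0.37 ± 0.17, Mthfd2 -1.27 ± 0.72, Atf4 -0.47 ± 0.47, Ppargc1a -0.28 ± 0.37, Atp2a2 0.05 ± 0.13 and Ppp3cb 0.12 ± 0.10. The genes with the smallest p, none of which passed (adjusted p from 0.542 to 0.708), were Lonrf3 (1.18 ± 0.17), Inhbb (1.31 ± 0.22), Gbp6 (1.41 ± 0.24), Armc7 (0.63 ± 0.11) and Mgst1 (0.63 ± 0.11) in the higher direction. In the lower direction they were Lpin3 (-0.85 ± 0.11), Bhlhe22 (-2.46 ± 0.38, at background after TAC and at least 3.02-fold lower), Vsig2 (-1.15 ± 0.21), the clock gene Per1 (-1.25 ± 0.24) and Olfr156 (-1.33 ± 0.26).

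In transgenic hearts camera called 8 gene lists for TAC against sham, each with 0 members past the threshold over all genes, and none of the 8 held with an estimated correlation (adjusted p from 0.317 to 0.892). The ATF4 and amino acid response list had a median of -0.58 over 29 genes (camera adjusted p = 1.12e-06, and adjusted p = 0.681 with an estimated correlation), with Atf3 at -1.58 ± 0.49. Relative to the wild-type sham mean, its level varied widely between transgenic sham arrays (mean 1.00, standard deviation 0.71), against 0.38 and 0.26 in transgenic TAC hearts. Fatty acid oxidation genes had a median of 0.17 (adjusted p = 0.756 with an estimated correlation), mitochondrial ribosome genes 0.09 (adjusted p = 0.892 with an estimated correlation), matrix genes 0.23 (adjusted p = 0.816 with an estimated correlation), fetal and hypertrophy genes 0.33 (adjusted p = 0.403 with an estimated correlation) and calcineurin and NFAT genes 0.12 (adjusted p = 0.441 with an estimated correlation). Circadian clock genes had a median of -0.40 (adjusted p = 0.317 with an estimated correlation), with 2 of 14 lower adjusted over the list alone, and serine and one-carbon genes -0.22 (adjusted p = 0.681 with an estimated correlation). Adjusted over the list alone, 0 genes of the other 7 lists passed. Of these 8 list calls, 2 were kept without transgenic sham array 1, and 4 each with slide as a block, quantile normalization or normexp background correction. Under median scaling 5 were kept, as without transgenic sham array 2, transgenic sham array 3 or transgenic TAC array 2. On slide 1, the only slide with transgenic arrays of both surgeries, the matrix, fetal and ATF4 medians were 0.18, 0.04 and -0.06, from 1 array against 1. With slide as a block they were 0.05, -0.01 and -0.19, and the matrix and fetal lists passed no threshold. The gene count was 3 without transgenic TAC array 3 and 1 with probes well above background on all 12 arrays.

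**Figure D1:**
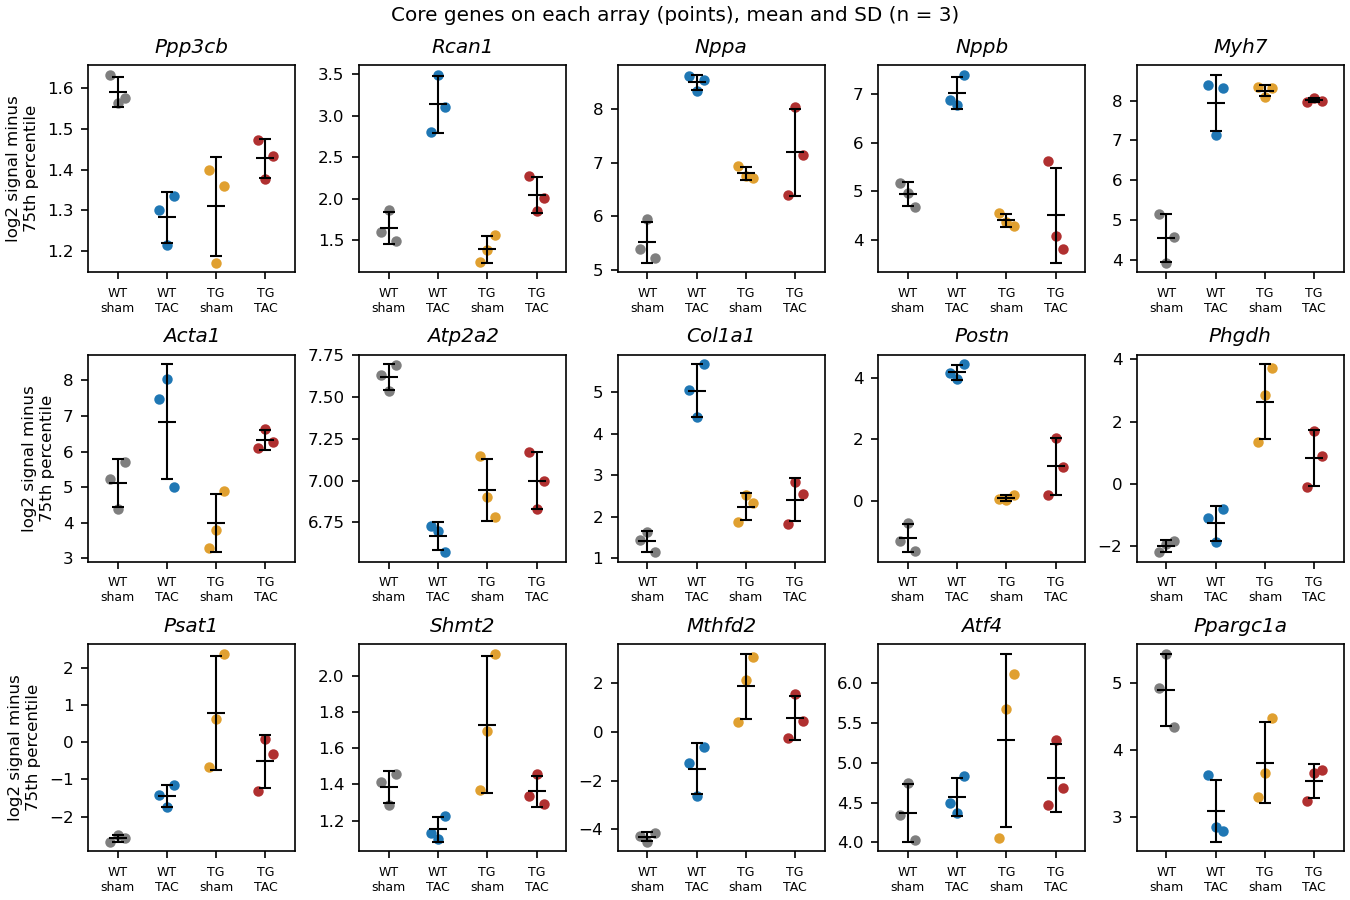
Log2 signal minus the array's 75th percentile for the core genes on each array, in wild-type (WT) and transgenic (TG) hearts after sham or TAC; points are arrays, bars are the mean and standard deviation of 3 arrays. Myh7 differed by 3.40 between TAC and sham in wild-type hearts and by -0.24 in transgenic hearts. Its level was already 8.09 to 8.34 on transgenic sham arrays, against 3.92 to 5.14 on wild-type sham and 7.14 to 8.40 on wild-type TAC arrays.

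The interaction of genotype and TAC tests whether the response to banding differed between transgenic and wild-type hearts. A negative value means a response that was less positive, or more negative, in transgenic hearts. Matrix and other secreted-protein genes had a lower response with the transgene: Chil1 (-6.78 ± 0.93), Comp (-6.39 ± 1.10), Frem1 (-6.23 ± 1.21), Ltbp2 (-5.93 ± 0.71), Cilp (-5.07 ± 0.66), Col5a2 (-4.48 ± 0.45), Thbs1 (-4.52 ± 0.83), Postn (-4.39 ± 0.57) and Col1a1 (-3.46 ± 0.49), with adjusted p from 0.0122 to 0.0239. Atp6v0a4 (-4.98 ± 0.93), Angptl7 (-4.60 ± 1.17) and Tmem200a (-4.56 ± 1.15) were further genes with a lower response. Chil1, Frem1 and Atp6v0a4 were at background in wild-type sham hearts, and Chil1 and Frem1 in transgenic TAC hearts as well, so their fitted values carry no exact size. Among fetal genes, Myh7 (-3.64 ± 0.50, adjusted p = 0.014) and Nppa (-2.58 ± 0.49, adjusted p = 0.0226) had a lower response, while Nppb (-1.97 ± 0.57) and Rcan1 (-0.84 ± 0.27) did not pass (adjusted p = 0.0641 and 0.0916). Mthfd2 also had a lower response (-4.06 ± 1.01, adjusted p = 0.0436), and Atp2a2 a higher one (1.01 ± 0.18, adjusted p = 0.0204). Myh7 and Mthfd2 were already higher, and Atp2a2 lower, in transgenic than in wild-type sham hearts. None of these genes passed for genotype after TAC. Higher responses included those of Cyp2b10 (5.23 ± 1.10), Acsm5 (4.70 ± 0.90), Retnla (4.58 ± 1.12), Scn4b (4.28 ± 1.10), Msln (3.79 ± 0.57), Ces1d (3.72 ± 0.86), Acot1 (3.58 ± 0.55), Clec18a (3.54 ± 0.65) and Klk1b16 (3.53 ± 0.91). Phgdh (-2.53 ± 0.85), Psat1 (-2.44 ± 0.90), Shmt2 (-0.13 ± 0.24), Atf4 (-0.67 ± 0.66), Ppargc1a (1.53 ± 0.52), Ppp3cb (0.42 ± 0.14) and Acta1 (0.59 ± 1.02) did not pass.

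By gene group, 37 of 47 matrix genes had a lower response in transgenic hearts and 0 a higher one, with 45 lower adjusted over the list alone. The median difference was -2.60 (camera adjusted p = 8.16e-39; adjusted p = 0.118 with an estimated correlation). Fibroblast markers differed in the same direction, with a median of -0.62, 2 of 11 past the threshold and 6 adjusted over the list alone (adjusted p = 0.118 with an estimated correlation). Of 78 oxidative phosphorylation genes 57 had a higher response, with 77 adjusted over the list alone, a median of 0.76 and Atp5c1 at 1.19 ± 0.18 (camera adjusted p = 3.56e-31; adjusted p = 0.166 with an estimated correlation). Of 28 fatty acid oxidation genes 26 had a higher response, and 26 adjusted over the list alone, with a median of 1.09 and Hadha at 1.49 ± 0.20 (adjusted p = 0.118 with an estimated correlation). The tricarboxylic acid cycle list had 11 of 18 higher, 18 adjusted over the list alone, and a median of 0.72 (adjusted p = 0.12 with an estimated correlation). Before scaling, the 75th percentile was 8.97 to 9.24 (log2) on wild-type sham and 9.88 to 9.95 on wild-type TAC arrays. It was 9.50 to 9.51 on transgenic sham and 9.48 to 9.86 on transgenic TAC arrays. The scaling subtracts these shifts, and the larger one in wild type raises the fitted interaction of every gene. How much of the higher medians comes from the scaling was not tested. Ion channel and calcium handling genes had 7 of 21 higher and 0 lower, 14 and 1 adjusted over the list alone, with Kcnj2 at 1.33 ± 0.17 and a median of 0.79 (adjusted p = 0.118 with an estimated correlation). Sarcomere genes had 7 of 21 higher, 12 adjusted over the list alone, with a median of 0.64 (adjusted p = 0.167 with an estimated correlation) that was 0.27 and past no threshold under quantile normalization. Fetal and hypertrophy genes had 3 of 10 lower, 6 adjusted over the list alone, with a median of -0.98 (adjusted p = 0.118 with an estimated correlation).

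Over all genes the interaction passed for 1793 of 25321, 1058 higher and 735 lower (59.0% higher), with 6466 at an unadjusted p under 0.05. The share higher was 40.3% of 913 genes under quantile normalization, 38.5% of 694 under median scaling and 48.8% of 1837 after normexp and quantile normalization together. It was 68.7% of 2218 with a common floor under the signals of all arrays, added after the data were seen, and 67.5% of 3319 with probes well above background on all 12 arrays. In limma the count was 0 with slide as a block, with 5876 genes at an unadjusted p under 0.05, and matrix, oxidative phosphorylation and fatty acid oxidation medians of -2.41, 0.84 and 1.17. It was 0 with normexp background correction, with 2960 genes at an unadjusted p under 0.05. The count fell to 141, 182 or 583 without wild-type sham array 3, 1 or 2, to 484 or 588 without wild-type TAC array 3 or 1, to 281 or 837 without transgenic TAC array 1 or 3, and to 871 without transgenic sham array 2.

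Averaged over both genotypes, 1875 genes passed for TAC against sham, 964 higher and 911 lower (51.4% higher). In a balanced design this average is independent of the interaction only where all groups have the same spread, and here the spread differed between groups. Large increases among genes named by the fixed rule included those of Cilp (3.74 ± 0.33), Comp (3.39 ± 0.55), Postn (3.22 ± 0.28), Ltbp2 (3.20 ± 0.36), Dio2, which activates thyroid hormone (2.77 ± 0.24), Col5a2 (2.69 ± 0.22), Dkk3 (2.61 ± 0.42), Lman1l (2.51 ± 0.31) and Mfap4 (2.44 ± 0.29). Large falls included those of Pde5a (-3.01 ± 0.79), Ciart, a clock gene (-2.09 ± 0.40), and Fam110c (-2.09 ± 0.31). Of the core genes, Rcan1 (1.07 ± 0.14), Nppa (1.68 ± 0.24), Nppb (1.09 ± 0.28), Myh7 (1.58 ± 0.25) and Acta1 (2.03 ± 0.51) rose on average. None of them passed in transgenic hearts alone, and the interaction passed for Nppa and Myh7. Of the 1875 genes 1800 (96.0%) had a smaller change in transgenic than in wild-type hearts, with a median size of 0.18 against 0.96, and 1503 (80.2%) had the same sign in both. Over all genes tested 67.3% had a smaller change in transgenic hearts, with median sizes of 0.18 and 0.35, and 47.7% had the same sign in both. Choosing genes on the average of both responses favours a shared sign, so the 80.2% is no separate evidence of a shared response. Across all genes, which are not independent replicates, the responses of the genotypes had a Pearson correlation of 0.012 and a Spearman correlation of -0.018. The share higher of the averaged comparison was 62.1% under quantile normalization, 63.0% after normexp and quantile normalization together and 81.1% of 122 genes with normexp background correction. It was 45.9% of 2852 genes with trended robust variance, 41.5% of 1878 with the common floor and 38.3% of 2706 with probes well above background on all 12 arrays. By camera 19 of 35 lists passed, with 38 of 47 matrix genes higher (median 1.41), 53 of 78 oxidative phosphorylation genes lower (-0.35) and 7 of 10 fetal and hypertrophy genes higher (1.05), the only list to pass with an estimated correlation (adjusted p = 0.0182). In limma the count was 0 with slide as a block, with 3420 genes at an unadjusted p under 0.05 there and 6075 without the block. It was 476, 934 or 637 without wild-type sham array 1, 2 or 3, 974 or 745 without wild-type TAC array 1 or 3, and 517 or 931 without transgenic TAC array 2 or 3.

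**Figure D2:**
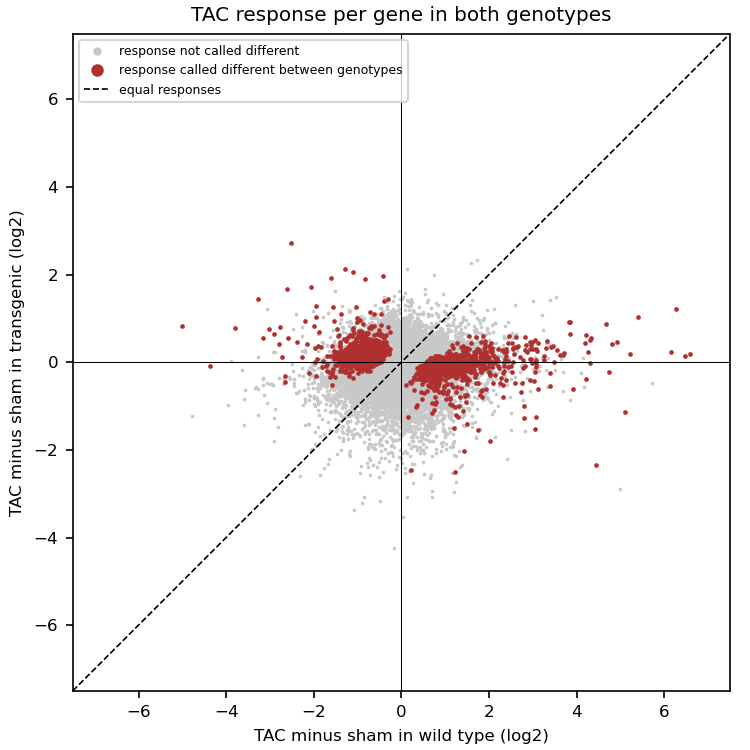
TAC minus sham in transgenic hearts (vertical axis, log2) against TAC minus sham in wild-type hearts (horizontal axis, log2), with a point for each gene tested; the 1793 genes with a different response by the interaction test are red. The dashed line marks equal responses, and across genes the Pearson correlation was 0.012.

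The genotype comparison in sham hearts asks what the transgene changes without banding. Among the genes that rose were Mthfd2 by 6.15 ± 0.72, Asns, which makes asparagine, by 5.28 ± 0.67, Phgdh, the entry enzyme of serine synthesis, by 4.64 ± 0.60, Aldh1l2 by 2.45 ± 0.36 and Aldh18a1 by 2.44 ± 0.41 (adjusted p from 0.00425 to 0.0267). The second probe of Phgdh measured 4.59. Fgf21, a secreted stress hormone, was at background in wild-type sham hearts and at least 19.7-fold higher in transgenic ones (adjusted p = 0.0124). Psat1, the next enzyme of serine synthesis, rose by 3.37 ± 0.64 (adjusted p = 0.0382) on its tested probe, while its other probe measured 1.34 and did not pass (adjusted p = 0.126). Myh7 was already 3.70 ± 0.36 higher in transgenic sham hearts (adjusted p = 0.00147), and Atp2a2 was lower (-0.67 ± 0.13, adjusted p = 0.0392). Shmt2 (0.34 ± 0.17), Atf4 (0.91 ± 0.47), Nppa (1.28 ± 0.35), Nppb (-0.54 ± 0.40), Col1a1 (0.83 ± 0.35), Postn (1.32 ± 0.40), Rcan1 (-0.26 ± 0.19), Acta1 (-1.11 ± 0.72), Ppargc1a (-1.09 ± 0.37) and Ppp3cb (-0.28 ± 0.10) did not pass. The design carries 1 probe for Ppp3cb, the gene of calcineurin A beta, and that probe need not detect the variant, so it says nothing about the level of the transgene.

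Further genes with higher signal in transgenic sham hearts were Tmem72 (at least 25.9-fold), Dlg4 (6.08 ± 0.19), Slc7a3, an amino acid transporter (5.22 ± 1.02), Pced1b (4.81 ± 0.19), Hspb9 (4.78 ± 0.28) and Gna15 (4.76 ± 0.17). Tmem72, Dlg4, Pced1b, Hspb9 and Gna15 have no other measured probe, and 0 of 7 genes with the same kind of constant difference showed it on their other probes. Lower in transgenic sham hearts were Msln, a mesothelial marker (-3.61 ± 0.40), Plekhh1 (-3.04 ± 0.52), Urah (-2.80 ± 0.41), Amy1 (-2.74 ± 0.43), Fah (-2.31 ± 0.35), Amy2a5 (-2.20 ± 0.38), Dbh (-2.12 ± 0.38), Egf (-2.10 ± 0.43) and Armc2 (-2.05 ± 0.42). Ano10 measured -2.13 ± 0.27 on its tested probe and -0.05 on its other probe, and the other probe of Amy2a5 measured -0.79. Neither other probe passed (adjusted p = 0.891 and 0.664). By the naming rule, none of the top genes overlapped between the 3 and 3 arrays.

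By gene group, the ATF4 and amino acid response list had 4 of 29 genes higher and 1 lower in transgenic sham hearts, with 15 and 1 adjusted over the list alone and a median of 0.91 (camera adjusted p = 1.19e-09; adjusted p = 0.332 with an estimated correlation). The gene that fell was Vldlr (-0.65 ± 0.10), a lipoprotein receptor. Serine and one-carbon genes had 4 of 23 higher, 7 higher and 3 lower adjusted over the list alone, and a median of 0.20 (adjusted p = 0.284 with an estimated correlation) that was 0.23 and past no threshold with slide as a block. Fatty acid oxidation genes had 12 of 28 lower, 26 adjusted over the list alone, and a median of -0.60, with Lpl at -0.89 ± 0.11 (camera adjusted p = 2.9e-20; adjusted p = 0.169 with an estimated correlation). Oxidative phosphorylation genes had 3 of 78 lower, 68 adjusted over the list alone, and a median of -0.39 (adjusted p = 0.284 with an estimated correlation). Before scaling, the 75th percentile was 9.50 to 9.51 (log2) on transgenic sham and 8.97 to 9.24 on wild-type sham arrays. The scaling subtracts this shift from every gene, and the shift is about as large as the oxidative phosphorylation median. Matrix genes had 0 of 47 past the threshold over all genes and 24 higher adjusted over the list alone, with a median of 0.76 and Col5a2 at 1.53 ± 0.32 (adjusted p = 0.332 with an estimated correlation). Ion channel and calcium handling genes had 4 of 21 lower, 11 adjusted over the list alone, with Trdn at -0.81 ± 0.10 and a median of -0.43 (adjusted p = 0.169 with an estimated correlation). Sarcomere genes had 1 of 21 lower, 12 adjusted over the list alone, and a median of -0.36 (adjusted p = 0.169 with an estimated correlation) that was -0.12 and past no threshold under quantile normalization. Tricarboxylic acid cycle genes had 1 of 18 lower, 13 adjusted over the list alone, and a median of -0.37 (adjusted p = 0.265 with an estimated correlation) that was -0.18 and past no threshold under quantile normalization. Neutrophil markers had a median of 2.15 over 7 genes with 0 past the threshold by either adjustment (camera adjusted p = 0.0489; adjusted p = 0.471 with an estimated correlation). That list call ended under median scaling (2.26, adjusted p = 0.0989), under quantile normalization (1.91, adjusted p = 0.0685) and with slide as a block (1.77, adjusted p = 0.321). The list's level on single arrays overlapped, at 1.69 to 3.00 in transgenic sham and -1.22 to 1.85 in wild-type sham hearts, relative to the wild-type sham mean.

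Over all genes 364 passed for the genotype difference in sham hearts, 196 higher and 168 lower (53.8% higher), with 194 changed by more than 2-fold. Quantile normalization gave 219 genes, 71.2% higher, median scaling 206 genes, 70.4% higher, and normexp background correction 40 genes, 77.5% higher. The balance turned the other way with the common floor (23.3% higher of 688), probes well above background on all 12 arrays (31.1% of 1122), trended robust variance (33.1% of 952) and without transgenic sham array 1 (38.9% of 627). The arrays did not overlap for 22.2% of genes, where chance gives 10%. Slide as a block gave 43 genes, 19 of them among the 364. On slide 2 the medians of the ATF4, matrix, oxidative phosphorylation and fatty acid oxidation lists were 1.00, 0.63, -0.46 and -0.64, from transgenic sham array 2, the array with the raised background, against 2 wild-type arrays, and with slide as a block 0.62, 0.48, -0.42 and -0.55. The count was 83, 92 or 82 without wild-type sham array 1, 2 or 3, 118 without transgenic sham array 2, 148 without wild-type TAC array 1, 172 without transgenic TAC array 3 and 627 without transgenic sham array 1.

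**Figure D3:**
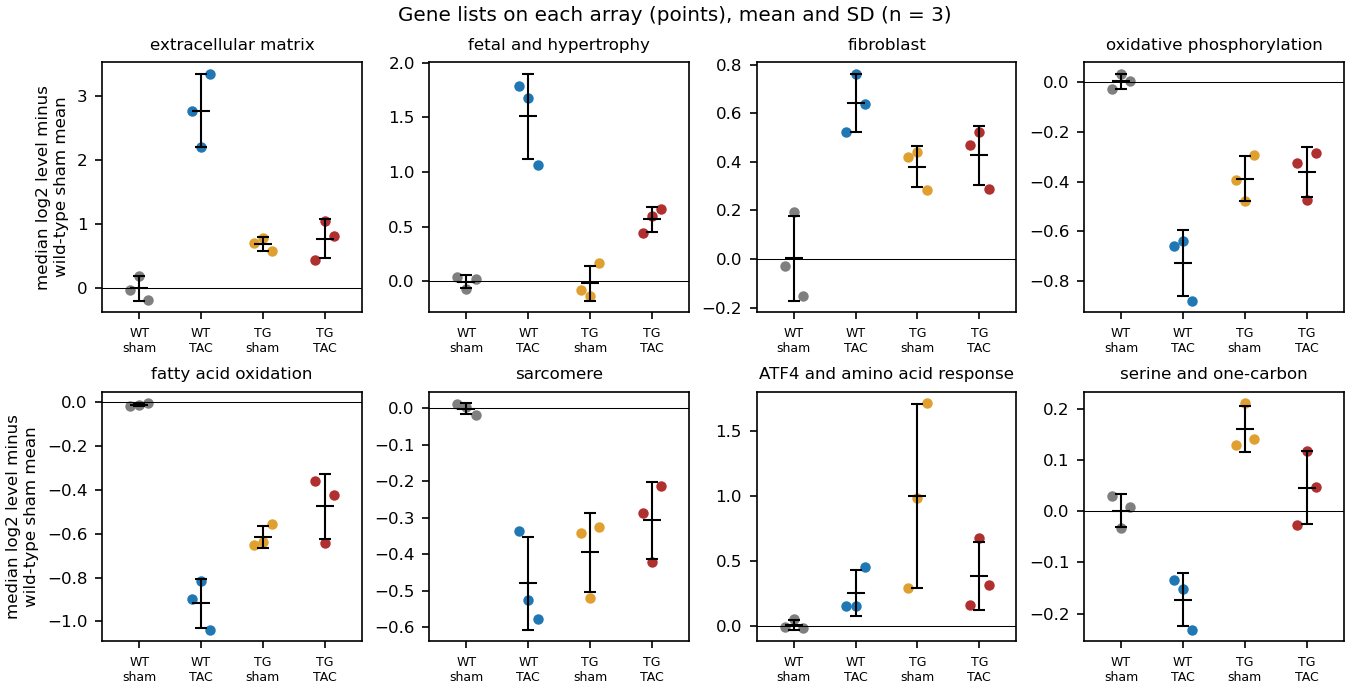
Median log2 level of the members of 8 gene lists on each array, relative to the mean of the wild-type sham arrays; points are arrays and bars the mean and standard deviation of 3 arrays. The matrix list stood at 2.77 in wild-type TAC hearts, 0.69 in transgenic sham hearts and 0.77 in transgenic TAC hearts; the wild-type change of the sarcomere list after TAC, a median of -0.43, turned to 0.05 under quantile normalization.

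The genotype comparison in banded hearts asks how transgenic hearts differed from wild-type hearts under the same operation. Matrix genes were lower in transgenic hearts: Comp by -5.89 ± 0.78, Ltbp2 by -3.96 ± 0.50, Fmod by -3.45 ± 0.74, Thbs4 by -3.37 ± 0.29, Postn by -3.07 ± 0.40 and Col1a1 by -2.63 ± 0.35 (adjusted p from 0.000546 to 0.0368). Cthrc1, Ecrg4, Frem1 and Chil1 were at background in transgenic TAC hearts and at least 21.7-fold, 44.7-fold, 11.6-fold and 9.04-fold lower there. Nppb (-2.51 ± 0.40, adjusted p = 0.0146), Ankrd1 (-1.60 ± 0.21, adjusted p = 0.00607) and Rcan1 (-1.10 ± 0.19, adjusted p = 0.0217) were lower as well. Nppa (-1.30 ± 0.35, adjusted p = 0.0665), Myh7 (0.06 ± 0.36), Acta1 (-0.52 ± 0.72), Atp2a2 (0.33 ± 0.13), Phgdh (2.11 ± 0.60, adjusted p = 0.0786), Psat1 (0.93 ± 0.64), Shmt2 (0.21 ± 0.17), Mthfd2 (2.09 ± 0.72), Atf4 (0.24 ± 0.47), Ppargc1a (0.44 ± 0.37) and Ppp3cb (0.14 ± 0.10) did not pass.

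Sfrp2 (-3.49 ± 0.75) and Ptx4 (-3.43 ± 0.72) were further genes with lower signal in transgenic TAC hearts. Higher there were Tmem72 (at least 42.4-fold), Dlg4 (5.70 ± 0.19), Hspb9 (5.17 ± 0.28), Gna15 (5.08 ± 0.17), the drug-metabolising enzyme gene Cyp2b10 (4.92 ± 0.77), Pced1b (4.85 ± 0.19), Plppr4 (4.75 ± 0.24), Klk1b22 (3.87 ± 0.62) and Retnla (3.39 ± 0.79). Tdg measured 3.31 ± 0.17 on its tested probe, but -0.40 and -0.60 on its other probes, which did not pass (adjusted p = 0.317 and 0.255). By the naming rule, none of the top genes overlapped between the 3 and 3 arrays.

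By gene group, 37 of 47 matrix genes were lower in transgenic than in wild-type hearts after TAC, 0 were higher and 10 did not pass, with 46 lower adjusted over the list alone. The median was -1.86 (camera adjusted p = 2.51e-42; adjusted p = 0.179 with an estimated correlation). Fetal and hypertrophy genes had 2 of 10 lower, 4 adjusted over the list alone, and a median of -0.60 (adjusted p = 0.179 with an estimated correlation). Fibroblast markers had 2 of 11 lower by both adjustments, Meox1 at -1.63 ± 0.29, and a median of -0.40 (adjusted p = 0.341 with an estimated correlation). Smooth muscle and pericyte markers had 3 of 10 lower, 4 lower and 2 higher adjusted over the list alone, Tagln at -1.39 ± 0.28, and a median of -0.33 (adjusted p = 0.462 with an estimated correlation). Endothelial markers had 1 of 12 lower, 5 lower and 1 higher adjusted over the list alone, and a median of -0.35 (adjusted p = 0.462 with an estimated correlation). Neither of these lists passed with normexp background correction, at -0.23 and -0.29. Oxidative phosphorylation genes had 6 of 78 higher, 63 adjusted over the list alone, and a median of 0.36, with Atp5c1 at 0.71 ± 0.13 (camera adjusted p = 8.71e-21; adjusted p = 0.429 with an estimated correlation). Fatty acid oxidation genes had 5 of 28 higher, 24 adjusted over the list alone, and a median of 0.46, with Acadl at 0.46 ± 0.09 (adjusted p = 0.341 with an estimated correlation). Tricarboxylic acid cycle genes had 2 of 18 higher, 11 adjusted over the list alone, and a median of 0.31 (adjusted p = 0.341 with an estimated correlation). Before scaling, the 75th percentile was 9.48 to 9.86 (log2) on transgenic TAC and 9.88 to 9.95 on wild-type TAC arrays. Subtracting it raises every gene in transgenic relative to wild-type hearts, by about as much as the oxidative phosphorylation and tricarboxylic acid cycle medians.

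Over all genes 1013 passed for the genotype difference in banded hearts, 542 higher and 471 lower, with 422 changed by more than 2-fold. The arrays did not overlap for 32.9% of genes, where chance gives 10%. Slide as a block gave 32 genes, 27 of them among the 1013, and normexp background correction 45. On slide 1 the matrix, oxidative phosphorylation and fatty acid oxidation medians were -1.93, 0.48 and 0.59, from 1 transgenic array against 2 wild-type arrays, and with slide as a block -1.88, 0.45 and 0.55. The count was 178, 293 or 449 without transgenic TAC array 1, 2 or 3, 258 or 196 without wild-type TAC array 1 or 3, and 424, 604 or 554 without wild-type sham array 1, 2 or 3. The balance moved both ways: 299 higher and 150 lower without transgenic TAC array 3, and 141 and 152 without transgenic TAC array 2. Of the genes that passed for genotype, 69 passed in both sham and banded hearts in the same direction and 30 in opposite directions. Calls independent between the comparisons would give 7.32 and 7.24. Both comparisons use the same spread of each gene, which can raise such overlap in either direction.

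Averaged over both surgeries 236 genes passed for genotype, 179 higher and 57 lower in transgenic hearts (75.8% higher). The share higher was 85.6% of 208 genes under median scaling, 65.7% of 356 after normexp and quantile normalization together, 55.2% of 460 with probes well above background on all 12 arrays and 45.0% of 302 with the common floor. The higher genes were led by Tmem72 (6.65 ± 0.25), Dlg4 (5.89 ± 0.14), Fgf21 (5.12 ± 0.66), Hspb9 (4.97 ± 0.20), Gna15 (4.92 ± 0.12), Pced1b (4.83 ± 0.13), Plppr4 (4.34 ± 0.17), Mthfd2 (4.12 ± 0.51), Asns (3.78 ± 0.47) and Psg20 (3.54 ± 0.54), and Phgdh rose by 3.37 ± 0.43. Tmem72, Fgf21 and Psg20 were at background in wild-type sham hearts, so their fitted values carry no exact size. The lower genes were led by Plekhh1 (-2.42 ± 0.37), Urah (-1.79 ± 0.29), Thbs4 (-1.78 ± 0.21), Msln (-1.72 ± 0.28), Nppb (-1.52 ± 0.28), Dio2 (-1.46 ± 0.24), Cgref1 (-1.34 ± 0.18), Dhrs4 (-1.27 ± 0.10), Hbegf (-1.27 ± 0.16) and Ankrd1 (-1.02 ± 0.15). Serine and one-carbon genes had 3 of 23 higher, 5 adjusted over the list alone, and a median of 0.19 (adjusted p = 0.674 with an estimated correlation). ATF4 and amino acid response genes had 2 of 29 higher, 12 higher and 1 lower adjusted over the list alone, and a median of 0.41 (adjusted p = 0.716 with an estimated correlation). The count was 53 with normexp background correction, 76 with slide as a block, and 149, 151 or 153 without wild-type sham array 1, transgenic TAC array 2 or wild-type sham array 2.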

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

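The slide comparison of the matrix genes, the comparison of other probes, the chromosome counts, the question of the genes without a name and both comparisons with the sarcomere list were tests chosen after the result was seen. The response to TAC differed between transgenic and wild-type hearts by the interaction test for 63 of the genes named in the text and for 18 gene lists. Of the genes, 29 had a lower and 34 a higher response in transgenic hearts (adjusted p from 0.0122 to 0.049 by limma).

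Lower responses among matrix and secreted factor genes were those of Chil1 (-6.78), Comp (-6.39), Frem1 (-6.23), Ltbp2 (-5.93), Cilp (-5.07), Angptl7 (-4.60), Thbs1 (-4.52), Col5a2 (-4.48), Dkk3 (-4.39), Postn (-4.39), Gdf15 (-4.33), Mfap4 (-3.78), Col1a1 (-3.46) and Thbs4 (-3.19). The other lower responses were those of Atp6v0a4 (-4.98), Tmem200a (-4.56), Mthfd2 (-4.06), Myh7 (-3.64), Bhlhe22 (-2.68), Nppa (-2.58), Dio2 (-3.80), Nupr1 (-3.11), the fibroblast markers Meox1 (-1.88) and Pi16 (-1.74), Vsig2 (-1.85), Igf1 (-1.73), Per1 (-1.39), Lpin3 (-1.31) and Ankrd1 (-1.16). Higher responses were those of Cyp2b10 (5.23), Acsm5 (4.70), Retnla (4.58), Scn4b (4.28), Msln (3.79), Ces1d (3.72), Acot1 (3.58), Clec18a (3.54), Klk1b16 (3.53), Amy1 (3.14), Ano10 (2.86), Amy2a5 (2.59), Fah (2.46), Gbp6 (1.80), Dhrs4 (1.42), Atp2a2 (1.01), Mgst1 (0.99), Gstm1 (0.88), Vldlr (0.85), Gstp1 (0.69) and Akt2 (0.58). Genes of energy metabolism with higher responses were, for fatty acid oxidation, Eci1 (1.51), Hadha (1.49), Lpl (1.03) and Acadl (0.82), and for oxidative phosphorylation, Atp5c1 (1.19), Sdhc (0.94) and Atp5a1 (0.79). Contractile, ion-handling and glucose transport genes with higher responses were Hrc (1.34), Kcnj2 (1.33), Slc2a4 (1.04), Trdn (0.95), Tnni3 (0.84) and Myh6 (0.67). Chil1, Frem1, Atp6v0a4 and Bhlhe22 were at background in wild-type sham hearts, and Chil1, Frem1 and Bhlhe22 in transgenic TAC hearts as well, so their fitted values carry no exact size.

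Among gene lists, lower median responses in transgenic hearts were those of extracellular matrix (-2.60), proliferation (-1.46), fetal and hypertrophy (-0.98), smooth muscle and pericyte (-0.86), ATF4 and amino acid response (-0.71), fibroblast (-0.62), endothelial (-0.44), inflammatory cytokine (-0.29) and macrophage and monocyte genes (-0.26). Higher ones were those of fatty acid oxidation (1.09), adult ion channel and calcium handling (0.79), oxidative phosphorylation (0.76), tricarboxylic acid cycle (0.72), sarcomere (0.64), mitochondrial ribosome (0.54), mitochondrial biogenesis and dynamics (0.52), glycolysis (0.46) and mitochondrial chaperone and protease genes (0.46). None of the 18 held with an estimated correlation (adjusted p from 0.118 to 0.48), and 14 of them passed fry. Under quantile normalization 4 of the 18 passed no threshold by camera: sarcomere (0.27), glycolysis (0.08), mitochondrial chaperone and protease (0.27) and inflammatory cytokine genes (-0.11). With probes well above background on all 12 arrays glycolysis (0.46), inflammatory cytokine (-0.07) and proliferation genes (-1.91) did not pass. Inflammatory cytokine (-0.40), macrophage and monocyte (-0.25) and proliferation genes (-0.91) did not pass with slide as a block. Their members past the threshold over all genes numbered 13 of 76 for the mitochondrial ribosome (51 adjusted over the list alone), 3 of 20 for mitochondrial biogenesis and dynamics (7), 3 of 13 for mitochondrial chaperones and proteases (6), 3 of 19 for glycolysis (11), 3 of 10 for smooth muscle and pericyte (6) and 2 of 12 for endothelial markers, with 5 lower and 1 higher adjusted over the list alone. The ATF4 list had 1 higher and 2 lower, with 2 and 5 adjusted over the list alone.

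Other groupings of the same arrays were fitted for each count. For the interaction, 1 of 100 drawn splits, the real one, gave as many genes: 1793, against 7 in the highest other drawn split. That share is under 0.05, so labels exchanged by chance, the slides set aside, are argued against for that count. The exchange of all genotype labels of the sham arrays was not among the draws. It is the averaged genotype comparison, with 236 genes. For TAC averaged over genotypes 4 of 100 drawn splits gave at least 1875 genes, a share under 0.05, with 3004 in the highest other drawn split. The splits above the real one kept the surgery labels of the wild-type arrays and mixed those of the transgenic arrays. The count thus does not show an effect of surgery in the transgenic arrays. For genotype averaged over surgeries 2 of 100 drawn splits gave at least 236 genes, a share under 0.05. The highest other drawn split, with 1793 genes, exchanges the genotype labels of the sham arrays and so is the interaction itself. These splits exchange labels without regard to the slides, which hold unequal parts of the groups, so they do not test a difference between slides. In limma with slide as a block the counts were 0 for the interaction and 0 for averaged TAC, with 5876 and 3420 at an unadjusted p under 0.05.

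For each comparison of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. The real split gave the highest count, at 1 of 10 splits, for TAC in wild-type hearts (5377 genes, highest other 0), for genotype in sham hearts (364, highest other 1) and for genotype in banded hearts (1013, highest other 0). For TAC in transgenic hearts all 10 of 10 splits gave at least the real count of 0, and the highest other gave 259. That split set transgenic sham arrays 1 and 2 and transgenic TAC array 3, from slides 1 and 2, against arrays from slides 3 and 4, so it follows the slides and points to a structure of the samples other than surgery. Slides alone need not be that structure: the split of sham arrays 1 and 3 and TAC array 3, from slides 1 and 3, against arrays from slides 2 and 4 gave 1 gene. With slide as a block limma counted 0 genes for TAC in transgenic hearts, with 979 at an unadjusted p under 0.05.

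The matrix genes had a median response of 2.78 in wild-type hearts, with quartiles of 1.93 and 3.73, and of 0.23 in transgenic hearts. The raised background of transgenic sham array 2 is argued against, since the transgenic median was 0.18 without that array. Mixed-up surgery labels among the transgenic arrays are argued against as well: over the other splits of those arrays the largest median was 0.32, below the lower quartile in wild type. A difference between slides as the whole source is argued against by arrays of the same group on different slides. Their medians for the list differed by at most 0.99, below the lower quartile of 1.91 of the sizes of the members' interaction. The interaction median was -2.41 with slide as a block, with quartiles of -2.92 and -1.77. Only 1 transgenic TAC array shared a slide with arrays of another group, so the block rests on few arrays. The genotype may account for the smaller response, and so could a smaller pressure load from the band, whose gradient was not analysed here.

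Between genotypes 54 genes, 27 of them named, differed by more than 2-fold in the same direction in sham and in banded hearts; 53 were higher in transgenic hearts and 1, Hbegf, was lower, and for all 54 the 6 and 6 arrays did not overlap. Of 7 such genes with another measured probe (C8g, Ephb6, Mif4gd, Mkrn1, P3h1, Sla2 and Tdg), 0 showed the difference there. That is consistent with hybridisation of single probes to another transcript, such as a strain variant or a transcript of the inserted DNA, as a hypothesis for genes such as Dlg4, Tmem72, Gna15 and Hspb9; a change of single transcripts of each gene was not tested. That 1 linked stretch of another strain's chromosome holds all 27 named genes is argued against. By gene order in GRCm38.p6 they lay on 13 chromosomes, with at most 5 on any of them. Of their pairs 0 lay within 5 tested genes of each other, with a mean of 0.21 and a 95th percentile of 1 in 10000 random sets. Random sets held so few such pairs that this count cannot exclude a stretch that holds some of the genes, or several stretches. For the 27 genes without a name a linked stretch and other sources cannot be told apart, since 0 of them were placed.

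In wild-type hearts after TAC the oxidative phosphorylation list had a median of -0.73 and the fatty acid oxidation list -0.92, while the sarcomere list had -0.43 (0.05 under quantile normalization). The fatty acid oxidation median lay below that of the sarcomere genes by a difference of -0.49 (95% bootstrap interval -0.91 to -0.16). The interval resamples list members and holds no spread between arrays, and the sarcomere median itself depended on the scaling. The comparison therefore cannot settle whether a smaller share of cardiomyocyte RNA accounts for the fall. For oxidative phosphorylation the difference was -0.30 (interval -0.67 to 0.000878), so its fall and a smaller share of cardiomyocyte RNA cannot be told apart, since the interval reaches 0. Scaling of the arrays may account for most of the oxidative phosphorylation fall, with a median of -0.29 under quantile normalization and -0.72 under median scaling. The fatty acid oxidation median stayed below 0 under the same settings, at -0.63 and -0.91. Both settings, like the main scaling, remove the shift in brightness between wild-type sham and TAC arrays. They therefore cannot tell whether scaling is the main source of the fatty acid oxidation fall.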

How the results depend on the processing

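Slide as a random block and a common floor were alternatives chosen after the data were seen, as were the slide-block tests of the gene lists. Of 888 values of genes in the fixed rule, 875 kept direction and side of the threshold with the deposited table, 562 with slide as a block (326 lost the call) and 660 with normexp background correction (222 lost it). Leaving out 1 array kept 9380 of 10656 values, with 1190 weaker, 86 stronger and 0 reversed. Signal over background limits the dim genes, most of all on transgenic sham array 2.

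Counts are given for TAC in wild-type, TAC in transgenic, genotype in sham, genotype in TAC, interaction, averaged TAC and averaged genotype, where they moved by over 1.5 times. Normexp background correction gave 1497 for TAC in wild type, 40 for genotype in sham, 45 for genotype in TAC, 0 for the interaction, 122 for averaged TAC and 53 for averaged genotype; limma counted 2960 interaction genes at an unadjusted p under 0.05. Quantile normalization gave 219 for genotype in sham and 913 for the interaction. Median scaling gave 206 for genotype in sham, 502 for genotype in TAC, 694 for the interaction and 1239 for averaged TAC. Normexp with quantile normalization gave 1750 for genotype in TAC and 356 for averaged genotype. Without a filter on dim probes the counts were 123 and 332 for genotype in sham and TAC, 484 for the interaction and 790 for averaged TAC. With probes well above background on all 12 arrays they were 1 for TAC in transgenic, 1122 and 2526 for genotype in sham and TAC, 3319 for the interaction and 460 for averaged genotype, with fewer genes tested. Trended robust variance gave 952 and 2190 for genotype in sham and TAC, 3036 for the interaction, 2852 for averaged TAC and 435 for averaged genotype. Array weights gave 9597 for TAC in wild type and 173 and 3144 for genotype in sham and TAC. The common floor gave 688 for genotype in sham. The cause was not tested except where stated.

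Slide as a block gave 524 for TAC in wild type, 43 and 32 for genotype in sham and TAC, 0 for the interaction, 0 for averaged TAC (5876 and 3420 at an unadjusted p under 0.05 in limma) and 76 for averaged genotype; it spends degrees of freedom on 5 slides that hold unequal parts of the groups. The main fit did not pair the arrays by their numbers. Between groups, pairs with the same number had a mean residual correlation of 0.035, and other pairs -0.017. Of the 18 pairs with the same number, 7 had a residual correlation above 0.1. These values do not settle whether the arrays were paired. A block on replicate number gave 113 and 363 for genotype in sham and TAC, 699 for the interaction, 861 for averaged TAC and 157 for averaged genotype. Fits to the compared groups alone, with fewer samples, gave 35 and 101 for genotype in sham and TAC, and unmoderated tests 19 and 22. Of 175 list tests in the first 5 of these comparisons 77 passed, and 1 with an estimated correlation. Of 35 lists each, 19 passed for averaged TAC, 1 of them, the fetal and hypertrophy list, with an estimated correlation (adjusted p = 0.0182), and 5 and 0 for averaged genotype.

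Leaving out 1 array in turn gave 2813 to 6207 genes for TAC in wild type, 0 to 3 for TAC in transgenic, 82 to 627 for genotype in sham, 178 to 1326 for genotype in TAC, 141 to 2357 for the interaction, 476 to 1908 for averaged TAC, 149 to 316 for averaged genotype and 63 to 79 list calls. Where it left 2 arrays in a group, the fit took the spread from all groups.

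Directions reversed, each past no threshold after the reversal, for Ahcy (0.16) and Foxo4 (0.36) in wild type after TAC and for Kif12 (0.27), Ostn (0.025) and Stra8 (0.18) in averaged TAC, all with normexp background correction. Aldoa in wild type after TAC turned to 0.055 under quantile normalization and 0.14 after normexp with quantile normalization. For lists, the direction is that of camera, which compares a list with the other genes. For TAC in transgenic hearts it reversed and passed with normexp for 4 lists: antioxidant (median -0.040), oxidative phosphorylation (-0.047), tricarboxylic acid cycle (-0.071) and glycolysis (-0.039). With slide as a block it reversed and passed for mitochondrial chaperone and protease genes (median 0.21) and immediate early genes (-0.80). The cause of these reversals was not tested. Normexp moved the median of all genes to 0.14 for TAC in transgenic, -0.14 for genotype in TAC and 0.19 for averaged TAC.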

Other observations

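Gene lists that the text above does not describe gave these values. In transgenic against wild-type sham hearts, fibroblast markers had a median of 0.40, with 0 of 11 past the threshold and 1 adjusted over the list alone (adjusted p = 0.236 with an estimated correlation), and smooth muscle and pericyte markers 0.20, with 0 of 10 past it and 4 adjusted over the list alone, Acta2 at 1.64 (adjusted p = 0.332 with an estimated correlation). Glycolysis genes had a median of -0.30, with 0 of 19 past it and 10 lower adjusted over the list alone (adjusted p = 0.332 with an estimated correlation); under quantile normalization the median was -0.11 and past no threshold (adjusted p = 0.763). Mitochondrial ribosome genes had a median of -0.27, with 0 of 76 and 3 (adjusted p = 0.471 with an estimated correlation), and mitochondrial chaperone and protease genes -0.23, with 1 of 13 and 2 (adjusted p = 0.471 with an estimated correlation). Macrophage and monocyte (0.19), endothelial (0.10) and proliferation genes (0.86) had 0 members past the threshold by either adjustment (adjusted p = 0.5, 0.471 and 0.511 with an estimated correlation). The macrophage, endothelial, proliferation and mitochondrial chaperone and protease lists each lost their camera call under median scaling (medians of 0.30, 0.21, 0.97 and -0.12) and with slide as a block (0.28, 0.30, 0.56 and -0.21).

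In transgenic against wild-type banded hearts, mitochondrial ribosome genes had a median of 0.29, with 2 of 76 higher and 1 adjusted over the list alone (adjusted p = 0.518 with an estimated correlation), and mitochondrial biogenesis and dynamics genes 0.26, with 2 of 20 higher, Esrrg at 0.57 and Esrrb at 0.58, and 4 adjusted over the list alone (adjusted p = 0.287 with an estimated correlation). Antioxidant genes had 3 of 30 higher, 7 higher and 2 lower adjusted over the list alone, and a median of 0.17, with Gstm1 at 0.71 and Gstp1 at 0.56 (adjusted p = 0.57 with an estimated correlation). Ion channel and calcium handling genes had a median of 0.26, with 1 of 21 higher and 5 adjusted over the list alone (adjusted p = 0.518 with an estimated correlation), and serine and one-carbon genes 0.30, with 1 of 23 higher and 3 adjusted over the list alone (adjusted p = 0.462 with an estimated correlation). Proliferation (-0.60), immediate early (-0.39) and mitochondrial chaperone and protease genes (0.23) had 0 members past the threshold by either adjustment (adjusted p = 0.57, 0.623 and 0.518 with an estimated correlation). With probes well above background on all 12 arrays the camera calls of the antioxidant (0.17), ion channel and calcium handling (0.17), serine and one-carbon (0.30), proliferation (-0.88), immediate early (-0.43) and mitochondrial chaperone and protease lists (0.24) ended. Under quantile normalization those of the antioxidant (0.09), ion channel (0.19), proliferation (-0.60) and chaperone lists (0.19) ended too. With slide as a block those of the antioxidant (0.26), ion channel (0.20) and proliferation lists (-0.30) ended. With normexp background correction those of the serine and one-carbon (0.09) and proliferation lists (-0.42) did. Without transgenic TAC array 3, 8 of the 16 list calls of this comparison were kept.

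Lists that did not pass camera for TAC in wild-type hearts had these medians: calcineurin and NFAT 0.03, with 2 of 13 higher and 1 lower, serine and one-carbon -0.17, ATF4 and amino acid response 0.20, antioxidant -0.24, with 4 of 30 higher and 13 lower, Akt, mTOR and FoxO -0.03, angiogenesis 0.09, with 6 of 17 higher and 2 lower, and circadian clock -0.23. Among other cell types they were T and NK cell -0.44, B cell -0.15, neutrophil -0.10, endocardial and mesothelial 0.02, atrial myocardium 0.50, adipocyte 0.09, erythroid -0.17, skeletal muscle 0.21, Schwann and nerve -0.59 and sex-linked genes -0.15. Of these, calcineurin and NFAT, antioxidant, atrial myocardium and Schwann and nerve genes passed fry (adjusted p = 0.0353, 0.0234, 0.0353 and 0.0234). Camera called the antioxidant list with normexp background correction (-0.36) and with the common floor (-0.24), and the Schwann and nerve list under quantile normalization (-0.60), under median scaling (-0.58) and with slide as a block (-0.82). Within the Akt list, Igf1 rose by 1.68 and Akt2 changed by -0.78. Igf1 was lower (-1.03) and Akt2 higher (0.42) in transgenic than in wild-type banded hearts.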
